A study of Mus musculus with 2 samples.

How the data were processed

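Gene expression was measured by RNA sequencing in stromal cells of mouse bone marrow, in 2 libraries. Per the labels' protocols, the cells were sorted after depletion of cells carrying CD45 (a surface protein of blood cells), lineage antigens or CD71 (the transferrin receptor, abundant on red cell precursors), and Calcein AM and DAPI were used to leave out dead cells. Although the series is titled as a single-cell study, the deposited table holds 1 value per gene and library, so each library was treated as 1 sample. The libraries were assigned to the groups BMT and aGVHD_V from their labels, and the meaning of the V is not given in the sources used here. 1 further column of per-sample values matched no sample label and was not used in any step.

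The values are FPKM (fragments per kilobase of gene length and of scaled library size) as deposited by the authors, per the file headers. The submitters' processing notes name edgeR 3.18.1 and the mouse builds GRCm38 and mm10. The aligner, the read counter and their settings, including whether strand was used, are not given in the sources used here. The table lists 54532 genes with Ensembl identifiers, symbols, positions, strand and length. Of these identifiers, 54409 were found in GENCODE release M21 (GRCm38), and 53499 of them (98.3%) had the same start and end there. Where rows shared a symbol, the row with the most reads was taken for that symbol.

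The authors' FPKM were multiplied by the deposited gene length and divided by 1000. The products were whole multiples of a fixed step in each library, for 100.0% of the values above 0 at a tolerance of 0.05, so the read number of each gene could be recovered. The recovered reads over genes summed to 10869191 in the BMT library and 11299834 in the aGVHD_V library. The steps correspond to library sizes of 12127105 and 10661688 reads, which are the recovered totals multiplied by 1.116 and 0.944. The authors' library sizes were thus scaled before deposit.

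The depth was uneven in another respect. Leaving out read numbers under 4, the most frequent read number of a detected gene (the highest sum over a moving window of 7 values) was 14 in the BMT library and 44 in the aGVHD_V library. Intervals that treat each read as independent would be too narrow if a starting molecule gave many reads. The reads of a gene were therefore divided by this modal number before an exact conditional binomial (Clopper-Pearson) 95% interval of the ratio was computed. These widened intervals cover counting error only, under the assumption that 1 modal number of reads stands for 1 count, and contain no variation between mice. The floor for a gene without reads was 3 counts per library, each of the modal read number, which is 42 reads in the BMT library and 132 reads in the aGVHD_V library. A fold against 0 reads is given as a lower bound against that floor, and no bound is given when both libraries are at or under it. A gene with reads in both libraries but under the floor in either is given by its values, without a fold.

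With 1 library per group no test between the groups was made and no p-value is given. The difference of a gene is log2(FPKM + 1) in the aGVHD_V library minus that in the BMT library, which understates the difference of low genes. Genes with an FPKM of 1 or more in at least 1 library were called measured, and a difference of 1 or more in either direction was counted as at least 2-fold. Folds of single genes are ratios of the FPKM without a pseudocount. For 34 gene lists of cell types, niche factors and pathways, the median difference over measured members was computed with its 95% order-statistic interval (the range where fewer than 6 members were measured). Each median was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean log2(FPKM + 1), as a description of these 2 libraries.

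The genes named were chosen by a fixed rule. It takes the 12 genes with the largest and the 12 with the smallest difference among genes with an FPKM of 10 or more in at least 1 library, leaving out unnamed predicted genes. It also takes, from each list, up to 4 measured members with the largest absolute difference and the member with the highest mean FPKM, and always Cxcl12, Kitl, Lepr, Cdh5, Pecam1, Ptprc and Tfrc. Values of some single genes are not reported here. The groups, the lists, this rule and 8 alternative settings were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, scaling of each library to an equal FPKM sum of 1000000, centring on the median of genes with an FPKM of 1 or more in both libraries, upper-quartile scaling, scaling without hemoglobin, mitochondrial and ribosomal protein genes, no filter, and an FPKM minimum of 5. 4 more were chosen after seeing the data: library sizes of all recovered reads, scaling of the aGVHD_V library alone to the FPKM sum of the BMT library, a minimum of 10 times the modal read number, and genes without reads set to their floor. Random lists matched on the BMT value and 7 further gene lists were likewise chosen after seeing the data.

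The steps were tested on simulated data made from the observed levels and depths of the BMT and aGVHD_V libraries. In these data 200 genes were changed 4-fold in either direction, drawn only from genes with a mean FPKM of 10 or more. With reads drawn one by one, 11953 genes were tested, 100.0% of the genes raised 4-fold and 100.0% of those lowered 4-fold were counted as at least 2-fold different in the right direction, and 100.0% of the read numbers were recovered. With reads drawn in groups of the modal read number, 12320 genes were tested and the shares were 99.0% and 92.0%. Detection of a change in genes with a lower mean FPKM was not simulated, so these shares do not cover them. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.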

Results

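The study profiled bone marrow niche cells, the non-blood cells that house and feed blood stem cells, after bone marrow transplantation with and without acute graft-versus-host disease (aGVHD), in which donor T cells attack the tissues of the recipient. Recipients were CB6F1 hybrid mice, irradiated with 2 doses of 4.0 Gy and given marrow from B6.SJL mice 4 hours later. Mice of the aGVHD group additionally received spleen cells from C57BL/6 mice. The files used here give 1 BMT library and 1 aGVHD_V library, so no difference between them has a replicate check. The recovered reads over genes numbered 10869191 in the BMT library and 11299834 in the aGVHD_V library. Reads were found for 15477 and 12310 genes, and 12048 and 10647 genes reached an FPKM of 1.

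The comparison of the libraries asks how niche cells of mice with aGVHD differ from those of mice that only received a transplant. What the V in aGVHD_V stands for is not given, so a further difference between the groups cannot be excluded. Transcripts of mesenchymal stromal cells, bone-forming cells, fibroblasts, extracellular matrix and B-lineage cells were lower in the aGVHD_V library. Hemoglobin, mitochondrially encoded and IgG heavy chain transcripts were higher there. All measured genes on the lists of neutrophils, MHC class I presentation and ribosomal proteins lay within 2-fold. Of 12942 measured genes, 2512 were at least 2-fold lower in the aGVHD_V library, 1119 were at least 2-fold higher and 9311 lay within 2-fold. Lower genes thus made up 69.2% of those outside 2-fold. Over the alternative settings this share ran from 56.3% to 87.1%. It was 56.3% (1009 lower, 782 higher) with genes without reads at their floor, 58.2% with an FPKM minimum of 5 and 58.6% with a pseudocount of 5. The share was 87.1% (3685 lower, 547 higher) when the aGVHD_V library alone was rescaled to the FPKM sum of the BMT library, which moved the median gene by -0.51 on the log2 scale. It was 84.5% (4374 lower, 800 higher) when each library was rescaled to an equal FPKM sum of 1000000, which moved the median gene by -0.56 and also raised all values against the pseudocount of 1. The median gene moved by -0.22 with library sizes of all recovered reads and by -0.15 with scaling without hemoglobin, mitochondrial and ribosomal protein genes.

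The direction depended on the level of expression. Among 7504 genes whose higher FPKM was between 1 and 10, 2097 were lower and 734 higher in the aGVHD_V library, whereas among 584 genes with an FPKM of 100 or more, 17 were lower and 71 higher. Of the 2512 lower genes, 1567 had no reads in the aGVHD_V library, and 378 of the 1119 higher genes had none in the BMT library. Across 9753 genes with an FPKM of 1 or more in both libraries, Pearson's r of log2(FPKM + 1) was 0.915 and Spearman's rho was 0.883, and genes are not independent replicates. In simulated libraries whose reads were drawn one by one, 20 of 11753 unchanged genes came out at least 2-fold lower and 19 at least 2-fold higher. With reads drawn in groups of the modal read number these were 1492 and 782 of 12120, so how far the single-gene counts lie within sampling error depends on whether reads come in such groups.

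**Figure D1:**
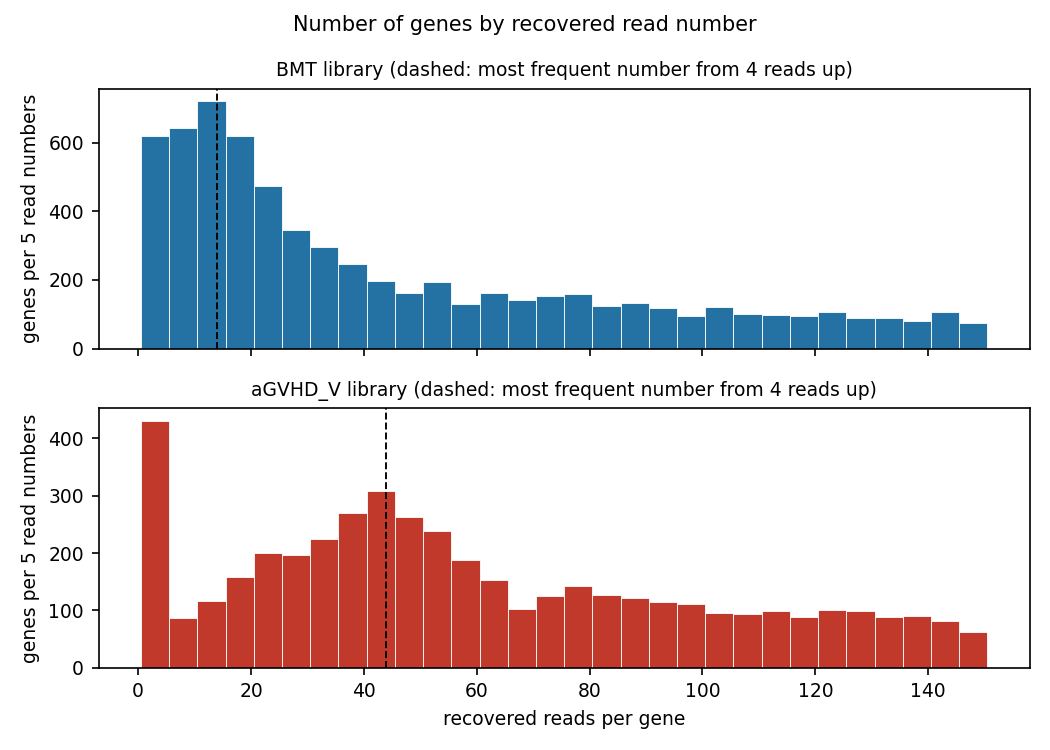
Number of genes (vertical axis, per 5 read numbers) by recovered reads per gene (horizontal axis, up to 150 reads) in the BMT library (upper panel) and the aGVHD_V library (lower panel); the dashed lines mark the most frequent read number from 4 reads up, 14 and 44. In the aGVHD_V library 431 genes had 1 to 5 reads and 87 had 6 to 10, and above 5 reads the highest bar stands at 41 to 45 reads.

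Transcripts of CXCL12-abundant reticular and mesenchymal stromal cells, the main source of stem cell maintenance factors in marrow, were lower in the aGVHD_V library. Of the 20 members of this list, all measured and 4 of them also on other lists, 18 were at least 2-fold lower and none was higher. The exceptions were Hp (haptoglobin) and Il1rn (interleukin 1 receptor antagonist, named after its values were seen). The median difference was -2.67 (95% interval over members -3.61 to -2.15), below the lowest of the 10000 random lists (-0.94). Cxcl12, the chemokine that retains stem cells in the marrow, had an FPKM of 346 in the BMT library and 14.6 in the aGVHD_V library, which is 23.8-fold lower (widened 95% interval 16.5 to 35.6). The gene (ENSMUSG00000061353) lies on chromosome 6 at 117168535 to 117181367 on the plus strand of GRCm38. Lepr, the leptin receptor that marks these cells (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352), had 2521 reads (FPKM 29.5) in the BMT library and none in the aGVHD_V library, at least 16.8-fold lower. Cxcl14, a chemokine of stromal cells, had an FPKM of 103 against 1.03 (interval of the fold from 9.81), and Adipoq, the hormone adiponectin, of 102 against 5.23 (interval 4.89 to 203). Hp had an FPKM of 337 against 248, 1.36-fold lower (interval 1.09 to 1.71).

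**Figure D2:**
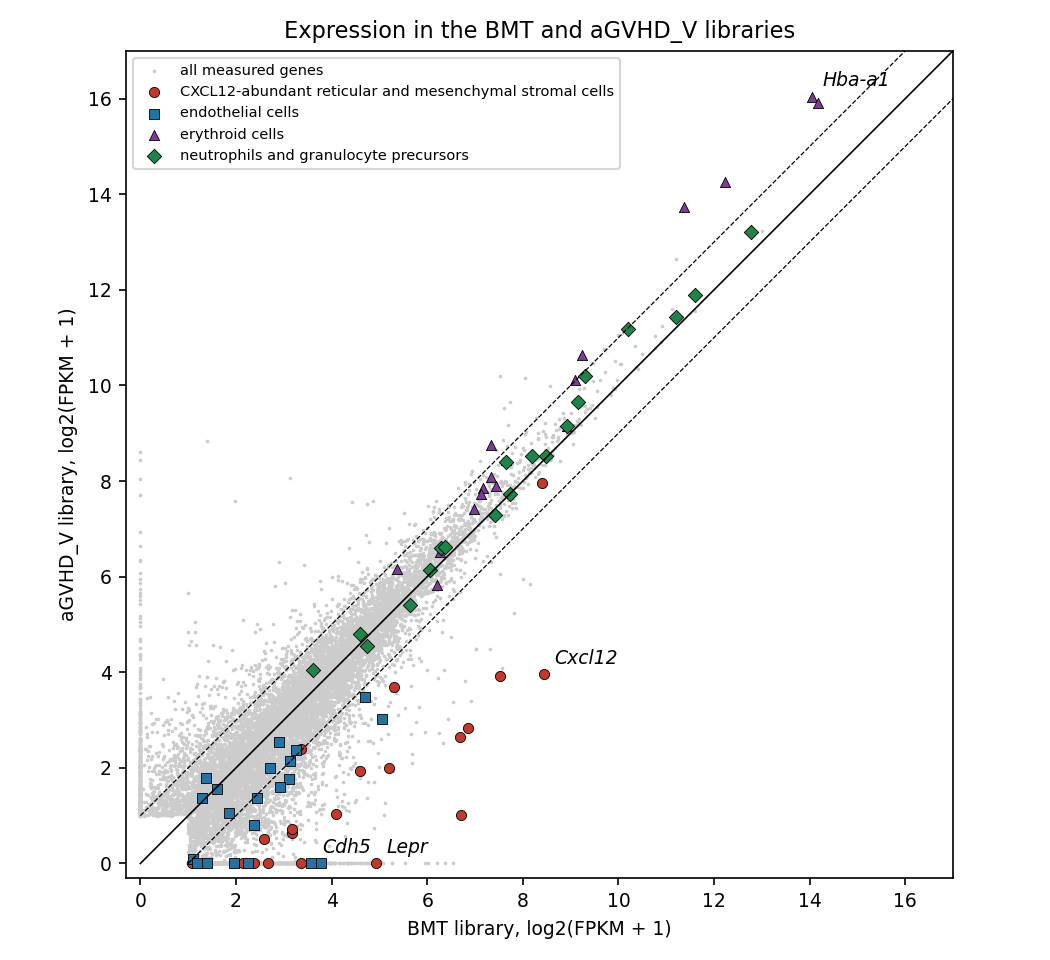
Expression of each of 12942 measured genes (grey points) in the BMT library (horizontal axis) and the aGVHD_V library (vertical axis), both as log2(FPKM + 1); coloured symbols are members of 4 gene lists, the solid line marks equal values and the dashed lines a 2-fold difference. Of 20 stromal genes (circles) 18 lie below the lower dashed line, including Cxcl12 (346 against 14.6), while the 19 neutrophil genes (diamonds) lie between the dashed lines and the hemoglobin genes above them.

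Factors that sustain blood stem cells showed the same direction, partly through shared members. Of 15 measured niche factors, 11 were at least 2-fold lower and none was higher, with a median of -1.62 (-2.54 to -0.82) against a lowest random list of -1.41. With genes without reads at their floor the median was -1.17, which is not below that list. The random lists were not set to the floor. Kitl, the stem cell factor, had an FPKM of 15.9 against 1.05 (interval of the fold 3.45 to 215). Spp1, the matrix protein osteopontin (55.5 against 8.71), was 6.38-fold lower (2.25 to 27.2), and the Notch ligand Jag1 was lower at 5.14 against 0.71 (1.19 to 297). Bmp4, a bone morphogenetic protein, had no reads in the aGVHD_V library and was at least 2.66-fold lower. Il6, a cytokine with an FPKM of 3.91 in the BMT library, also had none, and its level was too low for a bound.

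Genes of bone-forming cells and of the matrix were lower as well, partly through shared members. Of 14 measured osteolineage genes 13 were at least 2-fold lower and none was higher (median -1.84, -2.98 to -1.13, lowest random list -1.48). The exception was Postn (periostin, named after its values were seen), with an FPKM of 1.77 against 2.86. Other lists also held 5 of the 14 genes. Bglap, Bglap2 and Bglap3 of the osteolineage list, named after their values were seen, had no reads in either library. With genes without reads at their floor the osteolineage median was -1.44, which is not below the lowest random list. Col1a1 and Col1a2, the chains of type I collagen, were 9.37-fold lower (FPKM 23.2 against 2.47, interval 3.55 to 35.4) and 24.4-fold lower (33.9 against 1.39, interval 9.64 to 86.8). Ibsp, bone sialoprotein, had 262 reads in the BMT library and none in the other, at least 1.75-fold lower. Of 27 measured extracellular matrix genes 21 were lower and none was higher (median -2.46, -3.1 to -1.8, lowest random list -0.86). Other lists also held 7 of these 27 genes. Sparc, a collagen-binding protein, was 8.42-fold lower (110 against 13.05, interval 4.76 to 16.5), Bgn (the proteoglycan biglycan) 15.3-fold lower (50.02 against 3.28, interval 6.38 to 48.5) and Serpinh1 (a collagen chaperone) 13.4-fold lower (75.3 against 5.61, interval 4.73 to 59.3). Thbs1, thrombospondin 1, was at an FPKM of 104 against 62.8, 1.65-fold lower (interval 1.32 to 2.08).

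Fibroblast genes had a median of -2.28 (-3.2 to -1.23), below the lowest random list (-1.46), and 10 of 12 measured members were at least 2-fold lower. Those within 2-fold were Gsn (the actin-severing protein gelsolin) and Thy1 (a surface glycoprotein, named after its values were seen). Islr, a secreted or membrane protein of mesenchymal cells, had an FPKM of 33.3 against 1.01 (interval of the fold from 4.24). Dcn (decorin) was lower at 21.9 against 1.49 (interval 4.09 to 113) and Pcolce (an enhancer of procollagen processing) at 17.7 against 1.3 (interval 2.66 to 322). Of 11 measured adipocyte genes 8 were at least 2-fold lower and none was higher (median -1.33, -3.71 to -0.01, lowest random list -1.19). Among them Cebpa, a transcription factor of fat cells and of myeloid cells, was 4.0-fold lower (35.04 against 8.75, interval 1.72 to 11.7). Car3 (a carbonic anhydrase) had an FPKM of 18.6 against 0.49, and Cfd (adipsin) 25.1 against 6.61, and the interval of Cfd (0.779 to 57.8) included no difference. Of 15 chondrocyte genes 1 was measured, Comp (a cartilage matrix protein), with 154 reads in the BMT library and none in the aGVHD_V library, at least 1.03-fold lower.

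Endothelial transcripts were lower in the aGVHD_V library. Of 21 measured members 13 were at least 2-fold lower, 8 lay within 2-fold and none was higher, with a median of -1.19 (-1.57 to -0.78) at percentile 0.1 of the random lists. The median was -0.87 with genes without reads set to their floor, as 6 of the members had no reads in the aGVHD_V library. Cdh5, the junction protein VE-cadherin (ENSMUSG00000031871, chromosome 8, 104101625 to 104144511), had 557 reads (FPKM 10.9) in the BMT library and none in the aGVHD_V library, at least 3.71-fold lower. The tight junction gene Cldn5 (12.7 in the BMT library) and the VEGF receptor Kdr (3.76) also had no reads there and were at least 1.45-fold and 2.74-fold lower. Pecam1, the adhesion protein CD31, was lower at 7.65 against 2.41 (interval of the fold 1.11 to 13.3), and Plvap, a protein of vessel fenestrae, was 4.46-fold lower (32.0 against 7.17, interval 1.55 to 19.3).

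Pericyte and smooth muscle genes went both ways. 5 of 14 measured members were at least 2-fold lower, 2 were higher and 7 lay within 2-fold, with a median of -0.34 (-1.94 to 0.24) at percentile 19.2. Rgs5, a regulator of G protein signalling typical of pericytes, was 4.01-fold lower (62.6 against 15.6, interval 2.46 to 6.98). The other lower members were Kcnj8, a potassium channel subunit, its partner Abcc9, the actin-binding gene Cald1 and, named after its values were seen, Higd1b. Myl9, a myosin light chain of contractile cells, had an FPKM of 52.6 against 62.3. The higher members, Cnn1 and Lmod1 (muscle filament proteins, named after their values were seen), stayed below an FPKM of 4, and their intervals included no difference. Schwann cell genes had a median of -0.47 (-1.07 to 0.94) at percentile 17, with 4 of 10 measured members lower and 1 higher. Cnp, a gene of myelinating cells, was 2.16-fold lower (24.2 against 11.2, interval 1.11 to 4.7). Lower members also included S100b, with an FPKM of 1.61 against 0, and Pmp22, named after its values were seen, at 13.6 against 6.18 (interval of the fold 0.731 to 9.68, which included no difference). Sox10, the transcription factor of glial cells, was higher at 1.19 against 3.93 on 44 and 128 reads, with an interval of 0.437 to 23.9 that included no difference.

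Blood cell transcripts were abundant in both libraries although the sort had depleted CD45 and CD71. Ptprc, which encodes CD45, had an FPKM of 9.28 in the BMT library and 7.85 in the aGVHD_V library, 1.18-fold lower (interval 0.813 to 1.76). Tfrc, which encodes CD71, was 1.68-fold higher (160 against 269, interval 1.49 to 1.9). S100a9, a calcium-binding protein of neutrophils, had an FPKM of 6959 against 9474, 1.36-fold higher (interval 1.27 to 1.46) but lower with each library rescaled to an equal FPKM sum. Hemoglobin genes took 3.71% of the reads in the BMT library and 11.8% in the aGVHD_V library, and the 10 most abundant genes of each took 6.6% and 15.2%. The list of mesenchymal stromal cells took 0.736% of the reads in the BMT library and 0.078% in the aGVHD_V library. The neutrophil list took 1.75% and 1.92%. Lists of pathways active in many cell types therefore describe all sequenced cells together, and their values cannot be assigned to niche cells.

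Erythroid genes were higher in the aGVHD_V library, with a median of 0.78 (0.44 to 1.43) at the highest value of the random lists (0.78), and the median stayed above 0 (0.21) with each library rescaled to an equal FPKM sum. Of 17 measured members 7 were at least 2-fold higher and none was lower. Hba-a1, an alpha globin gene (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465), was 3.94-fold higher (FPKM 17046 against 67186, interval 3.84 to 4.04), and Hbb-bs, an adult beta globin gene, 3.32-fold higher (18547 against 61502, interval 3.23 to 3.4). The alpha and the beta globin genes are near-identical pairs, so the division of reads within a pair is uncertain. Megakaryocyte and platelet genes had a median of 0.79 (-1.2 to 1.38) at percentile 99.9, with 5 of 11 measured members higher and 3 lower, and the median was 0.24 over 13 genes without the filter. Pf4, platelet factor 4, was 6.72-fold higher (28.4 against 191, interval 3.67 to 12.7), Itga2b (the integrin CD41) 2.82-fold higher (7.38 against 20.8, interval 1.65 to 4.79) and Itgb3, its partner chain, 2.56-fold higher (3.34 against 8.55, interval 1.12 to 5.66). Gp9 and Gp5, subunits of the von Willebrand factor receptor, were at 10.1 against 25.3 and 2.78 against 6.92, with intervals of 0.672 to 8.61 and 0.47 to 11.5 that included no difference. Gp1ba, another subunit, was lower at 1.67 against 0, as were Tubb1 (8.5 against 3.14) and Treml1 (1.12 against 0), but the interval of Tubb1 (0.406 to 96.2) included no difference and the other genes had too few reads for a bound. Gp5, Tubb1 and Treml1 were named after their values were seen.

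No neutrophil or granulocyte precursor gene was at least 2-fold different on the log2(FPKM + 1) scale among 19 measured, and their median of 0.24 (0.02 to 0.44, percentile 58.5) became -0.34 with each library rescaled to an equal FPKM sum. Camp, an antimicrobial peptide of neutrophil granules, lay just under the threshold (1170 against 2335, 2.0-fold higher, interval 1.77 to 2.25). Pan-hematopoietic genes had a median of 0.16 (-0.07 to 0.41, percentile 45.3), which became -0.41 with that scaling. 14 of 15 members lay within 2-fold, and the exception was Runx3, a transcription factor of lymphoid cells, at 6.72 against 2.51 (interval of the fold 0.836 to 13.5, which included no difference). Monocyte and macrophage genes had a median of -0.05 (-0.69 to 0.38, percentile 27.9), and 15 of 17 measured members lay within 2-fold. The exceptions were Mrc1, a mannose receptor of tissue macrophages, 2.91-fold lower (8.22 against 2.83, interval 1.1 to 10.4), and Ms4a7, which was higher on 9 and 102 reads with an interval that included no difference. All 8 measured stem and progenitor cell genes lay within 2-fold (median -0.26, -0.95 to 0.57, percentile 39.2), among them Myb, a transcription factor of progenitors, at 14.2 against 6.86. Of 4 measured osteoclast genes (median 0.72, range -3.88 to 1.41, percentile 97.6, and 0.29 over 5 genes without the filter), the acid phosphatase Acp5 was 2.75-fold higher (20.1 against 55.4, interval 1.6 to 4.66), as was Itgb3. The collagenase cathepsin K gene Ctsk was at least 1.67-fold lower (13.7 against 0), and Nfatc1 lay within 2-fold.

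B-lineage genes were lower and IgG genes higher. Of 14 measured B and plasma cell genes 11 were at least 2-fold lower, with a median of -2.81 (-3.47 to -0.19) below the lowest random list (-1.71). The median was -0.5 with genes without reads set to their floor, because 7 of the members had no reads in the aGVHD_V library. Ighm, the heavy chain of IgM, was 11.7-fold lower (188 against 16.1, interval 5.7 to 28.5). Cd79b, a signalling chain of the B cell receptor, had 399 reads (FPKM 23) in the BMT library and none in the aGVHD_V library, at least 2.66-fold lower, and its partner Cd79a had 393 reads against 3, which is under the floor of 132 reads. Vpreb1, a surrogate light chain of B cell precursors, had an FPKM of 7.5 against 0. The only higher member was Jchain, which joins secreted antibody units (named after its values were seen), 6.15-fold higher on 52 and 281 reads (interval 1.46 to 30.9).

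In contrast, Ighg2c, a heavy chain gene of the IgG class made after class switching (ENSMUSG00000076612, chromosome 12, 113285325 to 113288932), was higher in the aGVHD_V library (FPKM 1.62 against 457, 26 against 6464 reads, interval of the fold from 73.8), with the BMT reads under the floor of 42. Ighg3, another IgG heavy chain gene, had no reads in the BMT library and 5603 (FPKM 209) in the aGVHD_V library, at least 152-fold higher. The variable genes with the largest differences were also found in a single library each. Igkv4-57 and Ighv1-53 had FPKM of 388 and 346 in the aGVHD_V library and no reads in the BMT library, at least 39.4-fold and 35.0-fold higher, and Igkv4-53, Ighv1-59 and Igkv3-2 followed at 261, 208 and 121. Igkv5-43, Igkv17-127, Ighv1-62-3, Ighv10-1 and Igkv1-110 had FPKM of 72.7, 63.6, 61.1, 37.4 and 32.5 in the BMT library and no reads in the aGVHD_V library, with lower bounds of the fold between 1.05 and 2.22. Of 53 measured immunoglobulin genes 16 were at least 2-fold higher and 37 lower. Immunoglobulin genes together nevertheless took a larger share of the reads in the aGVHD_V library, 0.23% against 0.073% in the BMT library. Variable genes share long stretches of sequence, so the assignment of reads among them is uncertain.

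T and NK cell genes had a median of 0.44 (0.09 to 1.01) at percentile 99.9, which became -0.06 with each library rescaled to an equal FPKM sum. Of 22 measured members 6 were at least 2-fold higher, 3 lower and 13 within 2-fold. Ccl5, a chemokine of activated T and NK cells, was the most abundant and was 1.9-fold higher (46.8 against 88.9, interval from just above 1 to 3.32). Cd3d, a chain of the T cell receptor complex, was at 0.95 against 6.77 (21 against 131 reads) and Prf1, the pore-forming protein perforin, at 0.61 against 4.83 (19 against 133 reads). The lower members were Ifng (interferon gamma, 5.86 against 1.01), its regulator Tbx21 (3.25 against 0) and the NK receptor gene Klrd1 (1.42 against 0, named after its values were seen). The intervals of Cd3d, Prf1 and Ifng included no difference, and the BMT reads of Tbx21 and Klrd1 were too few for a bound. Gzmb, the cytotoxic protease granzyme B (named after its values were seen), was 2.99-fold higher (13.8 against 41.4, interval 1.38 to 6.39).

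Among immune signalling genes, those of MHC class I presentation lay within 2-fold over all sequenced cells together. None of 15 was 2-fold different, and their median was -0.04 (-0.24 to 0.23, percentile 4.7), and -0.62 with each library rescaled to an equal FPKM sum. B2m, the light chain of MHC class I, had an FPKM of 1888 against 1929 (a ratio of 1.02, interval 0.912 to 1.14, below 1 with each library rescaled to an equal FPKM sum). MHC class II genes had a median of -0.14 (-0.92 to 1.34, percentile 5.3), with 7 of 10 measured members within 2-fold. Cd74, the invariant chain, was at 193 against 153 (1.26-fold lower, interval 0.932 to 1.74). The peptide-loading genes H2-DMb1 (5.28 against 14.9) and H2-Oa (0.94 against 4.35) had higher values, with intervals of 0.732 to 10.3 and 0.136 to 257 that included no difference, and H2-DMb2 (35 reads against 0) was under the floor in both libraries. Interferon-stimulated genes had a median of -0.13 (-0.6 to 0.33, percentile 5.6), and 24 of 31 measured members lay within 2-fold. Cxcl9, a chemokine that draws activated T cells, was 9.91-fold lower (92.5 against 9.33, interval 4.69 to 25.3), and Iigp1, an interferon-inducible GTPase, 3.25-fold lower (57.7 against 17.8, interval 1.86 to 6.17). Gbp5 (a guanylate-binding protein, 7.64 against 1.31), Socs1 (a brake on cytokine signalling, 4.79 against 0) and, named after its values were seen, Gbp3 (23 against 7.67) were also lower. Isg15, a ubiquitin-like modifier, was 2.45-fold higher (190 against 465, interval 1.83 to 3.25), and Ifit1 (named after its values were seen) was at 4.1 against 9.32, with an interval of 0.672 to 7.04 that included no difference.

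NF-kB and inflammatory cytokine genes had a median of -0.87 (-1.33 to -0.3) at percentile 0.0 of the random lists, and -0.25 with genes without reads set to their floor. 8 of 20 measured members were at least 2-fold lower, 11 lay within 2-fold and 1, Tnf (tumour necrosis factor, named after its values were seen), was higher at 12.4 against 26.5, with an interval of 0.893 to 4.83 that included no difference. The monocyte chemokine Ccl7 was at 11.6 against 0, Il1a (interleukin 1 alpha) at 6.98 against 0.76 and the endothelial adhesion gene Sele (E-selectin) at 3.6 against 0, all on too few reads to exclude equal levels. Nfkbia, the NF-kB inhibitor, was the most abundant and was 1.52-fold higher (163 against 248, interval 1.19 to 1.94). Co-stimulatory and checkpoint ligands had a median of 0.09 (-0.29 to 0.87, percentile 82.6), which became -0.36 with each library rescaled to an equal FPKM sum, and 8 of 10 measured members lay within 2-fold. Cd274, the checkpoint ligand PD-L1, was at 5.4 against 10.7 (1.99-fold higher, interval 0.794 to 4.67). Cd40 was lower (1.26 against 0) and Tnfsf9 higher (0 against 1.96), both on few reads.

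Immediate early genes, which are induced within minutes by signals or by tissue dissociation, had a median of -0.36 (-0.85 to 0.13), below the lowest random list (-0.17). 4 of 20 were at least 2-fold lower and none was higher. Egr1 was 12-fold lower (85.9 against 7.13, interval 5.98 to 28.6), Fos 5.06-fold lower (284 against 56.1, interval 3.54 to 7.47), Jun 2.79-fold lower (182 against 65.1, interval 2.09 to 3.81) and Socs3 2.63-fold lower (42.8 against 16.3, interval 1.43 to 5.35). Hspa1b, a heat shock gene with a near-identical copy, was at 214 against 283. Notch pathway genes had a median of -0.65 (-1.85 to -0.17, percentile 5.1), with 3 of 9 measured members lower and none higher. These were Jag1, the target gene Hes1 (19.1 against 4.14, interval 1.2 to 38.3), and Heyl, 2.44-fold lower (6.32 against 2.59, interval 0.778 to 11.7, which included no difference).

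Cell cycle genes had a median of 0.40 (0.27 to 0.56) at percentile 97.2, which became -0.16 with each library rescaled to an equal FPKM sum. 24 of 25 lay within 2-fold, and Birc5, a regulator of cell division, was 2.31-fold higher (47.7 against 110, interval 1.75 to 3.02). Mki67, a marker of dividing cells, was 1.75-fold higher (129 against 227, interval 1.58 to 1.94). Among p53 targets and apoptosis genes 17 of 19 lay within 2-fold (median -0.19, -0.6 to 0.49, percentile 6.8). Bbc3, the pro-apoptotic PUMA, was 2.66-fold higher (13.9 against 37.0, interval 1.39 to 5.01) and Plk2, a stress-induced kinase, lower at 6.24 against 1.17 (interval 1.02 to 112). Cdkn1a, the cell cycle inhibitor p21, was 1.91-fold lower (36.3 against 19.0, interval 1.13 to 3.43). Oxidative stress genes had a median of 0.13 (-0.14 to 0.45, percentile 44.1), -0.44 with the scaling to an equal sum, and 18 of 20 lay within 2-fold. Gpx1, the glutathione peroxidase inside cells, was 2.08-fold higher (1019 against 2123, interval 1.9 to 2.28), whereas Gpx3, its secreted relative, was 5.96-fold lower (129 against 21.6, interval 3.13 to 12.9).

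Unfolded protein response genes had a median of 0.25 (-0.3 to 0.5, percentile 78.0), -0.32 with the scaling to an equal sum, and 15 of 16 lay within 2-fold. The exception was Chac1, at 3.37 against 0, and Manf, a secreted stress factor of the endoplasmic reticulum, was 1.76-fold higher (29.9 against 52.6, interval 1.2 to 2.55). Glycolysis and hypoxia genes had a median of -0.02 (-0.51 to 0.18, percentile 21.1), from -0.59 to 0.01 over the scalings, and 17 of 18 lay within 2-fold. The exception was Ankrd37 at 1.07 against 0. Ldha, lactate dehydrogenase A, was at 200 against 205 (a ratio of 1.02, interval 0.854 to 1.22, below 1 with the scaling to an equal sum). Mitochondrially encoded transcripts had a median of 0.80 (0.55 to 1.17), near the highest of the random lists (0.87), and of 0.26 with the scaling to an equal sum. 4 of 13 were at least 2-fold higher and none was lower. The cytochrome oxidase subunit gene mt-Co1 was 2.69-fold higher (2361 against 6355, interval 2.55 to 2.84), and mt-Cytb, cytochrome b, 2.09-fold higher (832 against 1739, interval 1.86 to 2.34). The other higher members, mt-Co3 (8.2 against 19.7) and mt-Nd3 (3.32 against 15.9), were low in both libraries for mitochondrial genes and had intervals that included no difference, and copies of mitochondrial sequence in the nuclear genome make such values uncertain.

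All 24 ribosomal protein genes lay within 2-fold, and their median of 0.18 (0.13 to 0.29, percentile 20.7) became -0.4 with each library rescaled to an equal FPKM sum. All 15 housekeeping genes also lay within 2-fold, with a median of 0.09 (-0.04 to 0.28, percentile 15.6) that became -0.49 with that scaling. Eef1a1, a translation elongation factor, was at 3085 against 3006 (1.03-fold lower, interval 0.974 to 1.08), and Actb, beta actin, was 1.4-fold higher (581 against 811, interval 1.26 to 1.55) but lower with the scaling to an equal sum. Gapdh, a glycolytic enzyme, was low in both libraries (4.29 against 1.72), and its near-identical pseudogene copies make the value uncertain.

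**Figure D3:**
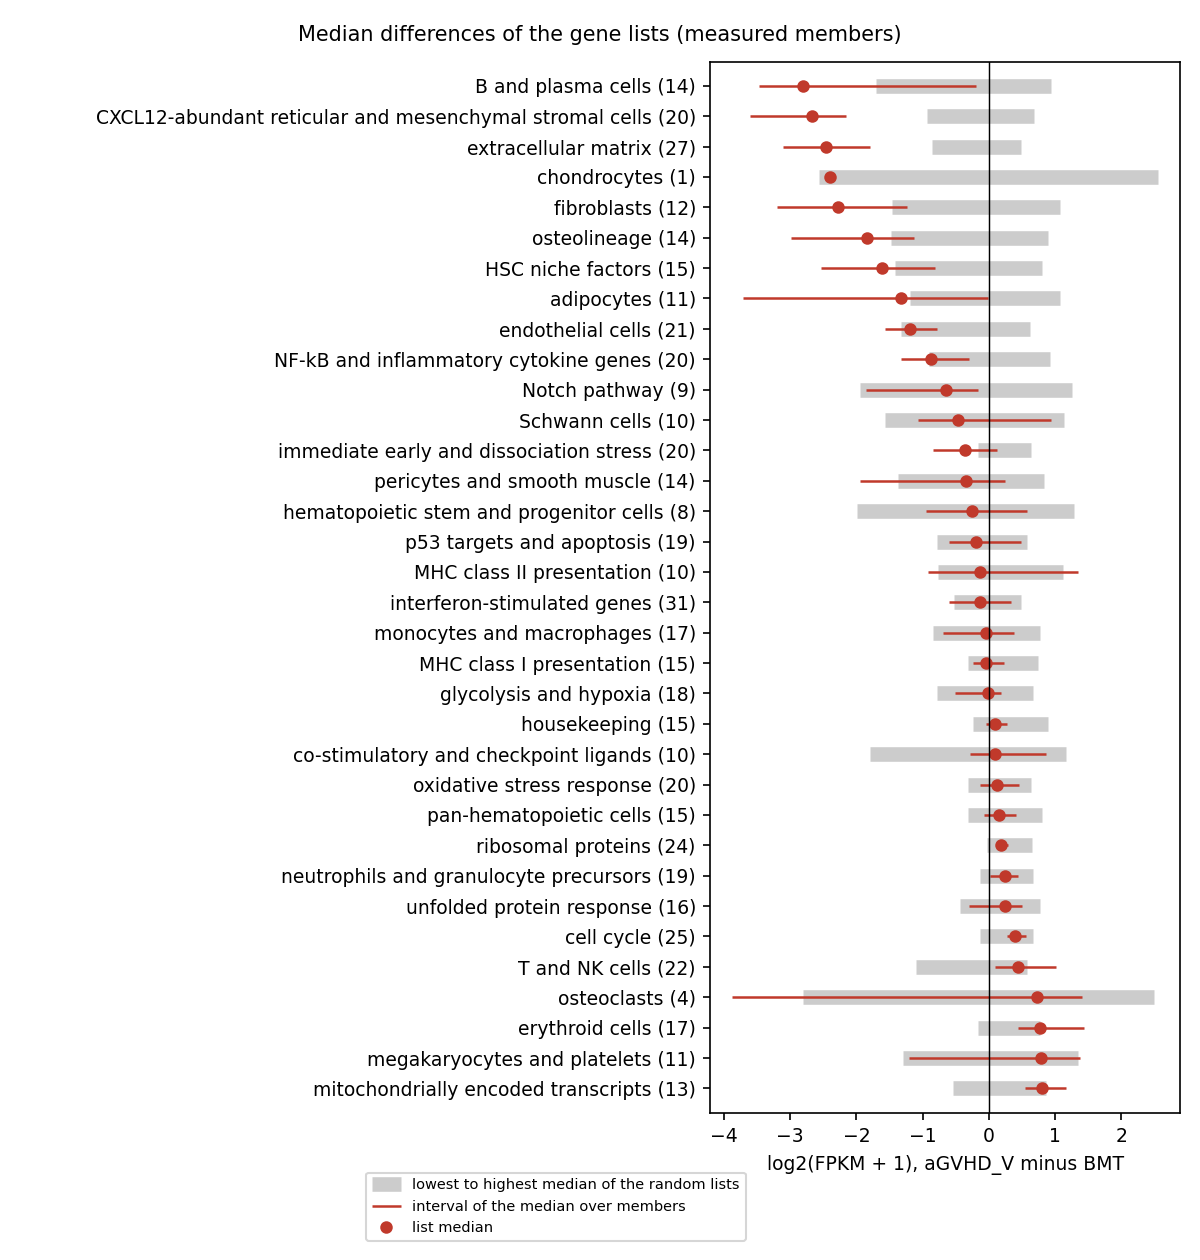
Median log2(FPKM + 1) in the aGVHD_V library minus that in the BMT library (horizontal axis) for 34 gene lists (vertical axis, measured members in parentheses); points are medians, red lines their 95% intervals over members and grey bars the lowest to highest median of 10000 random lists matched on expression. The medians range from -2.81 for B and plasma cells and -2.67 for mesenchymal stromal cells to 0.80 for mitochondrially encoded transcripts. Under some of the scalings run, 10 of the 34 change sign.

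Among the genes with the largest differences outside the lists, Esm1, a proteoglycan secreted by endothelial cells (ENSMUSG00000042379, chromosome 13, 113209659 to 113218098), had 2349 reads (FPKM 92.4) in the BMT library and none in the aGVHD_V library, at least 15.6-fold lower. C1ra, a protease of the complement cascade, had 958 reads (FPKM 26.5) against none and was at least 6.38-fold lower. The remaining genes at either end were short ones with few reads. The mitochondrial transfer RNA gene mt-Ts2, Mir7028, Mir5098 and the joining segment Trbj2-4 had 62, 54, 58 and 42 reads in the aGVHD_V library only, and the joining segment Igkj2 had 28. Snord58b (a small nucleolar RNA), Igkj1 and Ighj3 had 24, 21 and 15 reads in the BMT library only, fewer than the floor of 42 reads.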

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

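The settings named here as chosen after seeing the data were library sizes of all recovered reads, scaling of the aGVHD_V library alone to the FPKM sum of the BMT library, a minimum of 10 times the modal read number, and genes without reads at their floor; all others were fixed before the data were examined. Of 407 values of list medians under the alternatives, 342 stayed within the 95% interval over the list's members, and no median of at least 1 in size changed direction. Under some of the scalings run, 10 of the 34 lists, all with medians under 1 in size, changed sign. Of 1400 values of 175 named genes, 1133 moved by less than the error of the gene (its widened interval, or 1.5-fold where a library had no reads) and none reversed a difference of at least 2-fold. The count of genes at least 2-fold different was 356 higher and 503 lower with a pseudocount of 5, 616 higher and 859 lower with an FPKM minimum of 5 (8000 genes kept), and 232 higher and 1058 lower with a minimum of 10 times the modal read number (8950 genes kept). Under the minimum of 10 times the modal read number, unchanged genes of the simulated libraries also came out lower more often than higher with grouped reads. With reads drawn one by one, no unchanged gene under this minimum was at least 2-fold different. The excess of lower genes under this minimum can thus arise without a change if reads come in such groups. With genes without reads at their floor the count was 782 higher and 1009 lower. The count was 800 higher and 4374 lower with each library rescaled to an equal FPKM sum of 1000000, and 547 higher and 3685 lower with the aGVHD_V library alone rescaled. The pseudocount sets the size of differences of low genes by construction. With 0.1 the medians were -3.75 for CXCL12-abundant reticular and mesenchymal stromal cells, -2.66 for niche factors, -3.12 for osteolineage, -5.45 for the 1 chondrocyte gene, -1.63 for endothelial cells, -5.24 for B and plasma cells and -3.38 for extracellular matrix. With 5 they were -1.44 for the stromal cells, -0.83 for niche factors, -0.87 for osteolineage, -0.89 for the chondrocyte gene, -0.55 for endothelial cells, -1.25 for fibroblasts, -0.88 for adipocytes, -1.24 for B and plasma cells and -1.31 for extracellular matrix. Rescaling each library to an equal sum of 1000000 changes the ratio of the libraries and also raises all values against the pseudocount, so its moves are not those of the scaling alone. The medians were then -3.84 for the stromal cells, -2.75 for niche factors, -3.76 for the chondrocyte gene, -1.96 for endothelial cells, -1.09 for Schwann cells, -4.09 for B and plasma cells and -3.43 for extracellular matrix. In the blood and immune lists they were -0.41 for pan-hematopoietic cells, -0.06 for T and NK cells, 0.21 for erythroid cells, -0.34 for neutrophils, -0.62 for MHC class I, -0.7 for interferon-stimulated genes, -1.49 for NF-kB and cytokine genes and -0.36 for co-stimulatory and checkpoint ligands. In other lists they were -0.16 for cell cycle, -0.75 for p53 targets, -0.44 for oxidative stress, -0.32 for the unfolded protein response, -0.59 for glycolysis and hypoxia, -0.94 for immediate early genes, 0.26 for mitochondrial transcripts, -0.4 for ribosomal proteins and -0.49 for housekeeping genes. The last 10 lists stayed within their intervals, at -2.63 for osteolineage, -0.87 for pericytes, -3.14 for fibroblasts, -2.2 for adipocytes, 0.67 for megakaryocytes, -0.5 for monocytes, -0.83 for stem and progenitor cells, 0.28 for osteoclasts, -0.72 for MHC class II and -1.24 for the Notch pathway. With the aGVHD_V library alone rescaled, the stromal cells (-2.9), matrix (-2.62), B and plasma cells (-2.81) and the chondrocyte gene (-2.4) stayed within their intervals, and the medians that moved were -0.41 for pan-hematopoietic cells, -0.05 for T and NK cells, 0.21 for erythroid cells, -0.33 for neutrophils, -0.62 for MHC class I, -0.68 for interferon-stimulated genes, -0.16 for cell cycle, -0.65 for p53 targets, -0.42 for oxidative stress, -0.32 for the unfolded protein response, -0.57 for glycolysis and hypoxia, -0.92 for immediate early genes, 0.25 for mitochondrial transcripts, -0.4 for ribosomal proteins and -0.49 for housekeeping genes. The scalings by FPKM sum count hemoglobin genes, which took 3.71% of the reads in the BMT library and 11.77% in the aGVHD_V library. Scaling without hemoglobin, mitochondrial and ribosomal protein genes gave 0.24 for cell cycle, 0.01 for ribosomal proteins and -0.08 for housekeeping genes. It also gave 0.29 for T and NK cells, 0.07 for neutrophils and 0.08 for the unfolded protein response. Medians below 0 were -0.01 for pan-hematopoietic cells, -0.02 for co-stimulatory and checkpoint ligands, -0.03 for oxidative stress and -0.19 for glycolysis and hypoxia. Library sizes of all recovered reads gave -0.08 for pan-hematopoietic cells, -0.0 for neutrophils, -0.29 for MHC class I, 0.17 for cell cycle, -0.06 for ribosomal proteins, -0.15 for housekeeping genes and -2.53 for the chondrocyte gene. The chondrocyte gene was at -2.43 after centring on the median and at -0.04 at its floor, and the chondrocyte median over 5 genes without a filter was -0.53. Without a filter the megakaryocyte median was 0.24 over 13 genes, within its interval. With genes without reads at their floor the median of NF-kB and cytokine genes was -0.25. The floor of 132 reads in the aGVHD_V library limits what can be said of genes below that level, and an absence of reads there does not show absence of the transcript.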

Other observations

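The gene lists in the next paragraph, and the tests below of library scaling, of stromal cell numbers, of IgG reads, of plasma cells, of depth, of a filter and of amplification, were chosen only after the results they concern were seen; the test of fewer sampled molecules was set before its value was seen.

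Genes of 5 lists made after seeing the data, and the members named here, add to the picture of the report. All 10 measured matricellular, TGF-beta and BMP genes were at least 2-fold lower in the aGVHD_V library, with a median of -3.96 (95% interval over members -4.21 to -1.75) and of -2.4 with genes without reads at their floor. Cyr61, a matrix protein induced by YAP signalling, was 12.6-fold lower (FPKM 120 against 9.52, widened interval 5.17 to 41.3), Tnc (tenascin C) lower at 28.6 against 0.68 (interval 8.81 to 858) and Ctgf, a relative of Cyr61, at least 4.7-fold lower. Of 10 measured complement genes 7 were lower and none was higher (median -1.85, -4.34 to -0.25). Serping1 (the C1 inhibitor) was 6.01-fold lower (129 against 21.5, interval 3.39 to 11.7) and C4b 5.24-fold lower (81.1 against 15.5, interval 3.39 to 8.51), while C3 was at 98.2 against 82.4. Of 5 measured basophil and mast cell genes 3 were higher (median 1.19, range -0.29 to 1.88): the basophil proteases Mcpt8, 3.86-fold higher (16.5 against 63.7, interval 1.75 to 8.54), and Prss34, 2.31-fold higher (46.8 against 108, interval 1.43 to 3.67), and the IgE receptor chain Fcer1a (3.06 against 12.4), whose interval of 0.52 to 34.4 included no difference. Eosinophil genes did not share this direction, with a median of -0.47 (-1.1 to 0.61) over 7 measured genes and Prg2, the major basic protein, at 1727 against 1751. The constant genes of the T cell receptor were higher for both beta chains, at 5.95 against 23.7 for Trbc1 and 12.2 against 38.1 for Trbc2, and at 5.73 against 5.92 for the alpha chain gene Trac, on at most 281 reads and a median of 1.57 over 3 genes, and the interval of each included no difference.

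Transcripts of mesenchymal stromal cells were lower in the aGVHD_V library with a list median of -2.67. Library scaling as the whole explanation would move other lists as far. It is argued against by the medians of housekeeping genes (0.09) and ribosomal proteins (0.18), which lay near 0. The stromal median closest to 0 over the scalings run was -2.66. These scalings moved the median gene by -0.56 to 0.03 only, so they could not bring the list near 0 and do not decide this. Fewer sampled molecules would lower other genes of the same BMT level as far, but the lowest median of 10000 random lists matched on the BMT value was -0.74. Fewer stromal cells among the sorted cells would lower by a common fold only the members expressed in those cells alone. Of the 13 other members with reads in both libraries, the widened intervals of 9 held the fold of Cxcl12, too few to decide. Those of Hp, Vcam1, Il1rn and Igfbp5 did not. Blood cell transcripts were abundant in both libraries, and whether these members came from stromal cells alone was not tested. The 6 members without reads in the aGVHD_V library cannot be used for this comparison. A lower share of stromal cells, through the disease or through the sort, therefore cannot be told apart from lower expression per cell.

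IgG heavy chain transcripts were higher in the aGVHD_V library while most B-lineage transcripts were lower. In a list of heavy chain constant genes 2 of the 4 measured were higher (Ighg2c and Ighg3) and 2 lower (Ighm and Ighd, 2.95 against 0), with a median of 2.73 (range -3.47 to 7.72). Reads moving between near-identical IgG genes would leave their sum level, but summed IgG reads were 26 against 12067, a log2 ratio of 9.04 with a widened interval from 7.12. A larger number of plasma cells in general cannot be told apart from a few antibody-rich cells, because plasma cell genes other than immunoglobulins had a median of -0.63 (-1.59 to 0.11) over 10 genes that went both ways (3 of them on other lists), with Xbp1 at 39.25 against 24.3 and Jchain at 1.7 against 10.5. A few plasma cells left after the depletion of CD45 and lineage antigens, or antibody responses of mice with aGVHD, may each underlie the pattern, and neither was tested. Only mice of the aGVHD group received spleen cells, so the disease and this transfer cannot be told apart here.

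Leaving out read numbers under 4, the most frequent read number of a detected gene was 14 in the BMT library and 44 in the aGVHD_V library. A difference in depth is argued against by the ratio of total reads, 1.04, against a ratio of 3.14 between these modes. A filter on low read numbers is argued against by the genes with 1 to 5 reads, 431 in the aGVHD_V library and 621 in the BMT library. A small number of starting molecules, each amplified to many reads, would leave few genes between the lowest read numbers and the mode, and the fullest bin of 5 read numbers above 5 reads held 3.55 times the genes with 6 to 10 reads in the aGVHD_V library but 1.12 times in the BMT library, whose mode lies close to these numbers, so this explanation stays open. No biological explanation was tested for this pattern.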
